A study of Homo sapiens with 2 samples.

How the data were processed

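Total RNA of PC3 cells overexpressing ERG and of PC3 cells overexpressing ERG without the ETS domain was hybridised to 2 two-colour Agilent arrays of design 014850, each with 45015 spots. Per the labels, ERG RNA carried Cy5 and control RNA Cy3 on both arrays, and no array has the dyes swapped. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.1.1 under protocol GE2-v5_95_Feb07, and probe coordinates are on hg18. Both arrays lay on 1 slide read in 1 scan, so neither slide nor scan could be tested as a batch. How the cells were made to overexpress either form, and how RNA was extracted and labelled, is not given in the sources used here beyond a reference to the manufacturer.

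The scanner tables deposited for each array give the intensity of each spot and of its local background in both channels, per the file headers as mean pixel brightness and background median, without normalization. Per the file headers the software also made processed intensity values (background subtraction with a spatial detrend, then linear and LOWESS dye normalization, low spots set to a surrogate value), a log10 ratio of processed Cy5 over Cy3, and a p-value of that ratio from its error model for 1 array. The authors deposited a further table of log2 ratios, 1 column per array. Its values equal the log10 ratio turned to log2 within a tolerance of 0.0001 for 99.4% of 41000 probes, with a median of 0 in each column, but each column matches the scanner table of the other array (Pearson r = 0.999 with the other, 0.667 and 0.668 with its own). The scale, centring and direction of that table are therefore settled by the scanner values, while which replicate number is right is not, and no result below depends on the numbering. No column of per-sample values was left unused (0).

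Ratios were computed from the mean signal and background median of each channel with limma 3.58.1 in R 4.3.3: normexp background correction with an offset of 50, then loess within each array with control spots at weight 0. Control spots and spots with any outlier flag were left out (1506 and 1406 flagged spots on arrays 1 and 2), and the 10 spots of a repeated probe were averaged. Flagged spots were left out before the background model was fitted, an order settled after the data were examined. On array 2, 5 flagged spots lay over 1000 units below their local background, which reached 40951, and fitted on all spots the model's background SD was 441 in Cy3 and 425 in Cy5. With only these 5 left out it was 9.99 and 17.4, and without any flagged spot 0.793 and 0.578. The result of fitting all spots is given as an alternative. The offset shrinks ratios of dim probes, so the folds given understate the change of dim genes.

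A probe was tested if it was well above background on both arrays in at least 1 channel and had a value on both, which left 24135 probes. The brightest of a gene's probes stood for the gene, giving 17944 genes, of which 4769 had a further tested probe. Gene names are those of the scanner tables, brought up to date through a RefSeq gene table (assembly GRCh38.p14, names only): 11354 matched by accession, 1189 by symbol or synonym, and 5401 kept the file's name unmatched. For 809 genes the control channel and for 26 the ERG channel was not well above background on either array. Where such a gene is named, its fold is a lower bound, the bright channel against the higher of the dim probe's signal and the lowest signal well above background on that array, after loess and Aquantile scaling.

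Each gene's 2 log2 ratios were tested against 0 with limma's lmFit and eBayes (intercept only, two-sided, 1 residual degree of freedom plus 6.14 prior degrees of freedom, prior SD 0.0487) and adjusted by the Benjamini-Hochberg method, and a gene is called at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 12067 genes. As descriptions that do not rest on this test, genes at least 2-fold on both arrays were counted and the ratios of the arrays correlated across genes. The array is the block by construction, since each ratio is taken within an array. By the software's own error model, 1138 genes had p under 0.01 on both arrays in 1 direction, 642 of them with Cy5 higher. Spot noise was measured on 217 probes printed 10 times: the SD between spots of 1 probe was 0.064, and 12 of the 217 (5.53%) differed between arrays by more than the 95% range of that noise. Spike-in RNAs of 10 kinds gave measured against designed log ratios with slopes of 0.948 and 0.953, per the file headers. These slopes describe the scanner software's own log ratios, not those used here, and a slope does not check where 0 lies.

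Gene lists, 35 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The estimated correlation, ranks and fry were alternatives. With the estimated correlation, camera tests on the 1 residual degree of freedom and has very little power here. Within a list, genes were also adjusted over the list alone. The genes named are ERG, the 12 highest and the 12 lowest called genes with the same sign on both arrays and an official-looking symbol, up to 4 called members of each list by smallest p, and the brightest member of each cell type list, 154 genes in all, of which 1 is not reported here. Other genes are named as list members beside these or were chosen after their values were seen. Lists, tests, alternatives and this rule were fixed before the data were examined.

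The steps were tested on simulated data for ERG over ETS-deleted ERG: among 17944 genes at the measured intensities, 200 were changed. Of 50 genes changed by 0.3 on the log2 scale 46 (92%) were called, and all 50 at each of 0.6, 1 and 2. The mean measured sizes were 0.23, 0.48, 0.79 and 1.62. Of 17744 unchanged genes 17 were called, 7.98% of all calls. The simulated spot noise was independent between arrays. No gene-specific dye effect shared by both arrays, density trend or difference between RNA preparations was simulated. The share of false calls in the measured data is therefore not given by this test.

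Alternatives were no background subtraction, an offset of 16, the processed signals, the deposited table, median centring, Aquantile scaling, no filter on dim probes, both channels well above background, the mean of all probes, eBayes with trend and robust, no array block, other thresholds and each array alone. A further 3 were added after the data were examined: a background model on all spots, feature flags only with a model free of flagged spots, and removal of the gene density trend. Local gene density is the number of array genes within 500 kb on either side of a probe.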

Results

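Gene expression was measured in PC3 cells, an established human prostate cancer line that grows without androgen. Cells overexpressing ERG, an ETS-family transcription factor that gene fusions activate in many prostate cancers, were compared with PC3 cells overexpressing ERG without its ETS domain, the part that binds DNA. The comparison asks which transcripts depend on the DNA-binding domain of the overexpressed protein. The 2 RNAs shared each of 2 two-colour oligonucleotide arrays, numbered replicate 1 and 2, and ERG RNA carried Cy5 on both, so a dye effect that both arrays share cannot be told from an effect of ERG. Each array held 43376 gene spots for 41000 probes. In the control channel 60.2% and 60.6% of gene spots lay well above background on arrays 1 and 2, and in the ERG channel 66.6% and 63.5% did. No spot was saturated. Nothing in the labels says that the replicates came from separate cultures. The arrays differed by no more than the noise between spots: over 217 probes printed 10 times, the SD of the difference between array means was 0.0294 on the log2 scale, against 0.0301 from spot noise alone. They may therefore be 2 hybridisations of 1 pair of RNAs and are read as 1 biological comparison measured on 2 arrays. Each SD (n = 2 arrays) and each adjusted p of a gene or probe below may thus describe only the spread between hybridisations. The number of arrays limits the precision. The adjusted p of a gene list at the preset correlation sets its members against the spread among genes instead. It likewise says nothing of the spread between cultures.

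The overexpressed gene was covered by 3 ERG probes on chromosome 21 (hg18), and their ratios differed. Probe A_24_P922378, at 38677643 to 38677702, was higher with full-length ERG by a log2 ratio of 0.84 ± 0.034 (SD, n = 2 arrays), or 1.79-fold, with an adjusted p of 5.97e-06 over all tested probes. In the scanner software's processed signals the same probe was 4.79-fold higher. With the background model fitted on all spots its log2 ratio was 0.46 and the call ended (adjusted p = 0.201). Probe A_23_P301414, at 38696356 to 38696415, gave a log2 ratio of -0.08 ± 0.021 and did not pass (adjusted p = 0.0789). Under median centring, which raised the median of all genes, it passed above 0 (0.23, adjusted p = 0.000425) but stood at -0.067 relative to the median of all genes, and it passed as lower with the gene density trend removed (-0.14, adjusted p = 0.00796). It is the brightest ERG probe and stands for the gene in the counts below. The third probe, A_23_P57323 at 38676351 to 38676410, was not well above background on either array. Which part of the transcript each probe matches was not established here. A probe in the part shared by both overexpressed forms would detect both, and one in an untranslated part would see only the endogenous gene. Only a probe in the part that encodes the ETS domain could tell the 2 forms apart. Since it is not known here whether any probe lies there, these values do not check the labels.

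By size, 82 genes differed at least 2-fold on both arrays, 70 of them higher and 12 lower with full-length ERG. The count was 436, with 367 higher, in the scanner software's processed signals, 300, with 298 higher, when each array was centred on its median, and 24, with 22 higher, with the background model fitted on all spots. The highest were MGAT4A, a Golgi enzyme that branches N-glycans, at a log2 ratio of 2.88 ± 0.0039 (7.35-fold, SD over 2 arrays here and below), and IGFBP5, a secreted binding protein of insulin-like growth factors, at 2.58 ± 0.11 (5.97-fold). ICAM2, an adhesion molecule of endothelium, was higher by 2.49 ± 0.13 and KLF2, a zinc-finger transcription factor of endothelium, by 2.39 ± 0.038. ITGB3, the integrin beta-3 subunit, reached 2.36 ± 0.0053 and TGFBI, a secreted matrix protein induced by TGF-beta, 2.31 ± 0.063. KALRN reached 2.32 ± 0.059, the homeobox gene HOXB9 2.29 ± 0.0068 and the ankyrin repeat gene ANKRD1 2.16 ± 0.068. RASIP1, which vessels need to form a lumen, was higher by 2.12 ± 0.016, the transcription factor TCF15 by 2.09 ± 0.083 and the dehydrogenase DHRS9 by 2.03 ± 0.052.

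The lowest gene was ADGRF1, an adhesion G protein-coupled receptor, at a log2 ratio of -1.75 ± 0.03 (3.37-fold lower). CST1 (-1.37 ± 0.092) and CST2 (-1.02 ± 0.016), which encode salivary cystatins, were lower together. AREG, a ligand of the EGF receptor, was lower by a log2 ratio of -1.08 ± 0.065, and FGFBP1, which releases fibroblast growth factors from the matrix, by -1.09 ± 0.048. PDAP1 stood at -1.30 ± 0.021, the annexin ANXA6 at -1.21 ± 0.043 and PKIB, an inhibitor of protein kinase A, at -1.16 ± 0.092. Cardiac troponin I (TNNI3) was at -1.12 ± 0.035, the death receptor TNFRSF21 at -1.07 ± 0.027, the T cell receptor segment TRBV5-4 at -1.03 ± 0.049 and emerin (EMD) at -1.02 ± 0.075. Adjusted p-values of these 24 genes lay between 6.24e-08 and 2.62e-06. In hg18, the MGAT4A probe lies on chromosome 2 at 98608629 to 98608688, the ICAM2 probe on chromosome 17 at 59433692 to 59433751 and the ADGRF1 probe on chromosome 6 at 47075804 to 47075863.

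**Figure D1:**
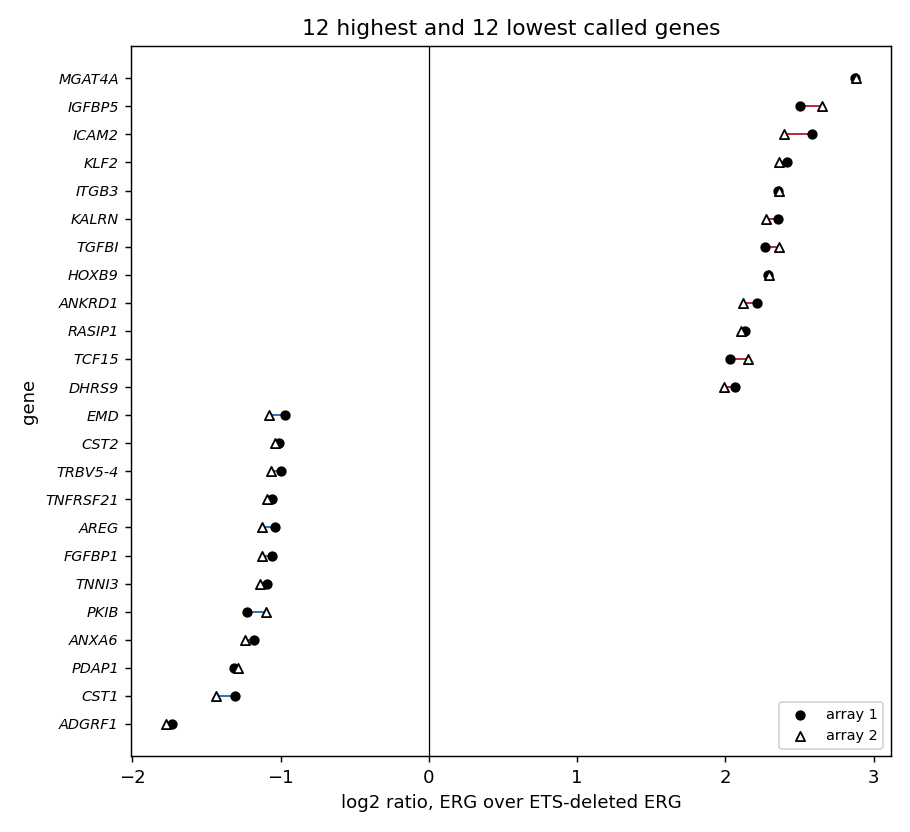
The log2 ratio of ERG over ETS-deleted ERG (x axis) is shown for the 12 highest and 12 lowest called genes, 1 row per gene, with array 1 as filled circles and array 2 as open triangles joined by a line. MGAT4A lies at 2.88 and ADGRF1 at -1.75, and the arrays lie close together for every gene shown.

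Other probes of the same gene gave smaller ratios for several of these genes. A second, dimmer KLF2 probe stood at 0.12, a second TCF15 probe at 0.17 and a second KALRN probe at 0.48, all with intensities where the offset in the background model shrinks ratios. Whether shrinkage accounts for the whole gap was not tested. GIMAP1, at a mean log2 intensity of 6.65 against 6.545 for that KLF2 probe, still reached 1.16. The folds of KLF2, TCF15 and KALRN therefore rest on 1 probe each. So do those of genes without a further tested probe. Among the highest these are MGAT4A, ICAM2, TGFBI, HOXB9, ANKRD1, RASIP1 and DHRS9. Among the lowest they are CST1, CST2, ANXA6, PKIB, TNNI3, FGFBP1, AREG, TRBV5-4 and EMD. The further probes of ITGB3 (1.87 and 1.03), IGFBP5 (1.88), ADGRF1 (-0.83), TNFRSF21 (-0.87) and PDAP1 (-0.52) kept the sign of the brightest probe. All 25 genes with a ratio of 2-fold or more and a further tested probe had the same sign on it.

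Across all 17944 tested genes, limma's test against no change called 11368, 6105 higher and 5263 lower. Of these, 95.7% were under 1.5-fold, with a median absolute log2 ratio of 0.21, and 492 were both called and at least 1.5-fold different, 297 higher and 195 lower. The ratios of the arrays correlated across genes (Pearson r = 0.946, Spearman rho = 0.911), genes not being independent replicates, and 15607 genes (87.0%) had the same sign on both. The count rests on a background model fitted without the spots that the scanner software flagged. With the model fitted on all spots and only spots flagged as feature outliers left out, 1894 genes were called, against 11945 with that flag rule but the model fitted without flagged spots. Without the array as a block 4904 were called. Median centring in place of an intensity-dependent dye correction moved the median of all genes from 0.015 to 0.29 and the share of calls that were higher from 53.7% to 85.8%.

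**Figure D2:**
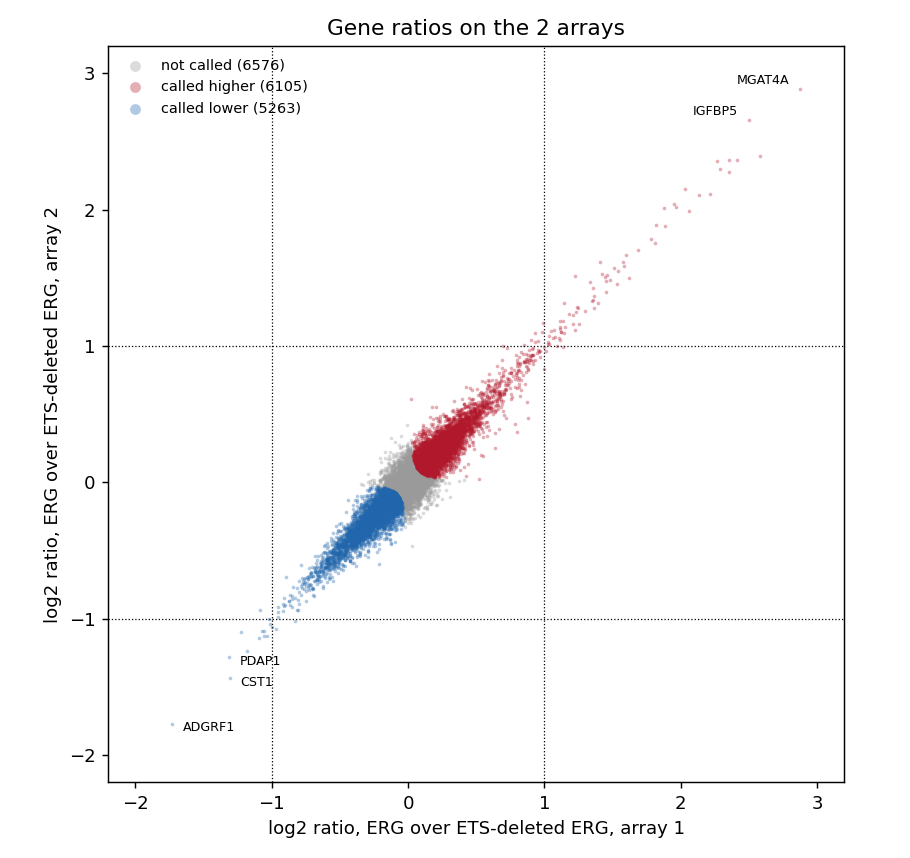
Each point is 1 of 17944 tested genes, placed by its log2 ratio of ERG over ETS-deleted ERG on array 1 (x axis) and array 2 (y axis) and coloured by limma's call. Dotted lines mark 2-fold, and 70 genes lie beyond them upward and 12 downward on both arrays.

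Gene lists written before the data were examined showed 4 of 35 lists shifted against all other genes by limma's camera test at a preset correlation, all upward. None held with an estimated correlation (adjusted p = 0.724 for each), and at the preset correlation the count ran from 2, in the processed signals, to 10, under median centring. With an estimated correlation the test has only 1 residual degree of freedom and could hardly call any list, so these losses decide nothing. The oxidative stress list lost its call though its estimated correlation, -0.053, lay below the preset 0.01. Its unadjusted camera p was 0.0033 at the preset and 0.193 at the estimated correlation. Relative to all genes, the medians of 13 lists turned sign under another scaling, 11 of them under median centring, and those of the 4 shifted lists did not. The lists on ERG targets and on cytokines lead. Of the published ERG-activated genes, 15 of 19 tested rose, 1 fell and 3 passed in neither direction (adjusted p = 0.00173, and adjusted p = 0.724 with an estimated correlation). Beside ICAM2, they included PLAT, the tissue plasminogen activator, at 1.54 ± 0.0054, LEF1, a WNT-responsive transcription factor, at 1.495 ± 0.053 and MMP9, a matrix metalloproteinase, at 1.07 ± 0.0096. CXCR4 stood at 1.06, PLAU at 0.50, VIM at 0.15 and YAP1, the member that fell, at -0.19. VWF, CDH5, EPHA3, MMP3, KCNN2 and TDRD1 were not tested, being dim, and EZH2 was left out because its spot was flagged. Whether any member was first named from these arrays is not known here. Genes higher in prostate tumours with an ERG fusion had 5 of 9 higher and none lower (adjusted p = 0.108), among them GHR (0.44 ± 0.026), AMPD3 (0.45 ± 0.071), PLA1A (0.47 ± 0.19) and MYO6 (0.20 ± 0.05).

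Of 22 tested members of the NF-kB and inflammatory cytokine list 15 were higher, 3 were lower and 4 passed in neither direction (adjusted p = 0.00173, and adjusted p = 0.724 with an estimated correlation). The neutrophil-attracting chemokines CXCL1 (1.48 ± 0.07), CXCL3 (1.15 ± 0.047) and CXCL2 (1.11 ± 0.013) led, with the colony-stimulating factor CSF3 at 0.92 ± 0.025. IL11 stood at 0.99, IL1B at 0.85, CCL2 at 0.79 and LIF at 0.78, while CSF2 (-0.42), BIRC3 (-0.35) and NFKB2 (-0.14) fell. In the oxidative stress and metallothionein list, 14 of 19 rose and 4 fell (adjusted p = 0.0388, and adjusted p = 0.724 with an estimated correlation). Haem oxygenase 1 (HMOX1) was higher by 1.24 ± 0.014 and the metal-binding proteins MT2A by 0.86 ± 0.10 and MT1G by 0.67 ± 0.03, while AKR1C3, a steroid-metabolising reductase, was lower by a log2 ratio of -0.77 ± 0.017. The unfolded protein and integrated stress response list had 14 of 26 higher and 3 lower (adjusted p = 0.0479, and adjusted p = 0.724 with an estimated correlation). Its members included ATF3 (0.97 ± 0.097), TRIB3 (0.66 ± 0.054), HSPA5, the main chaperone of the endoplasmic reticulum (0.54 ± 0.0061), and DNAJC3 (0.41 ± 0.037). ATF4 (0.05), XBP1 (0.08) and ASNS (-0.01) did not pass. The calls of these stress lists ended in the scanner software's processed signals (adjusted p = 0.173 and 0.186).

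**Figure D3:**
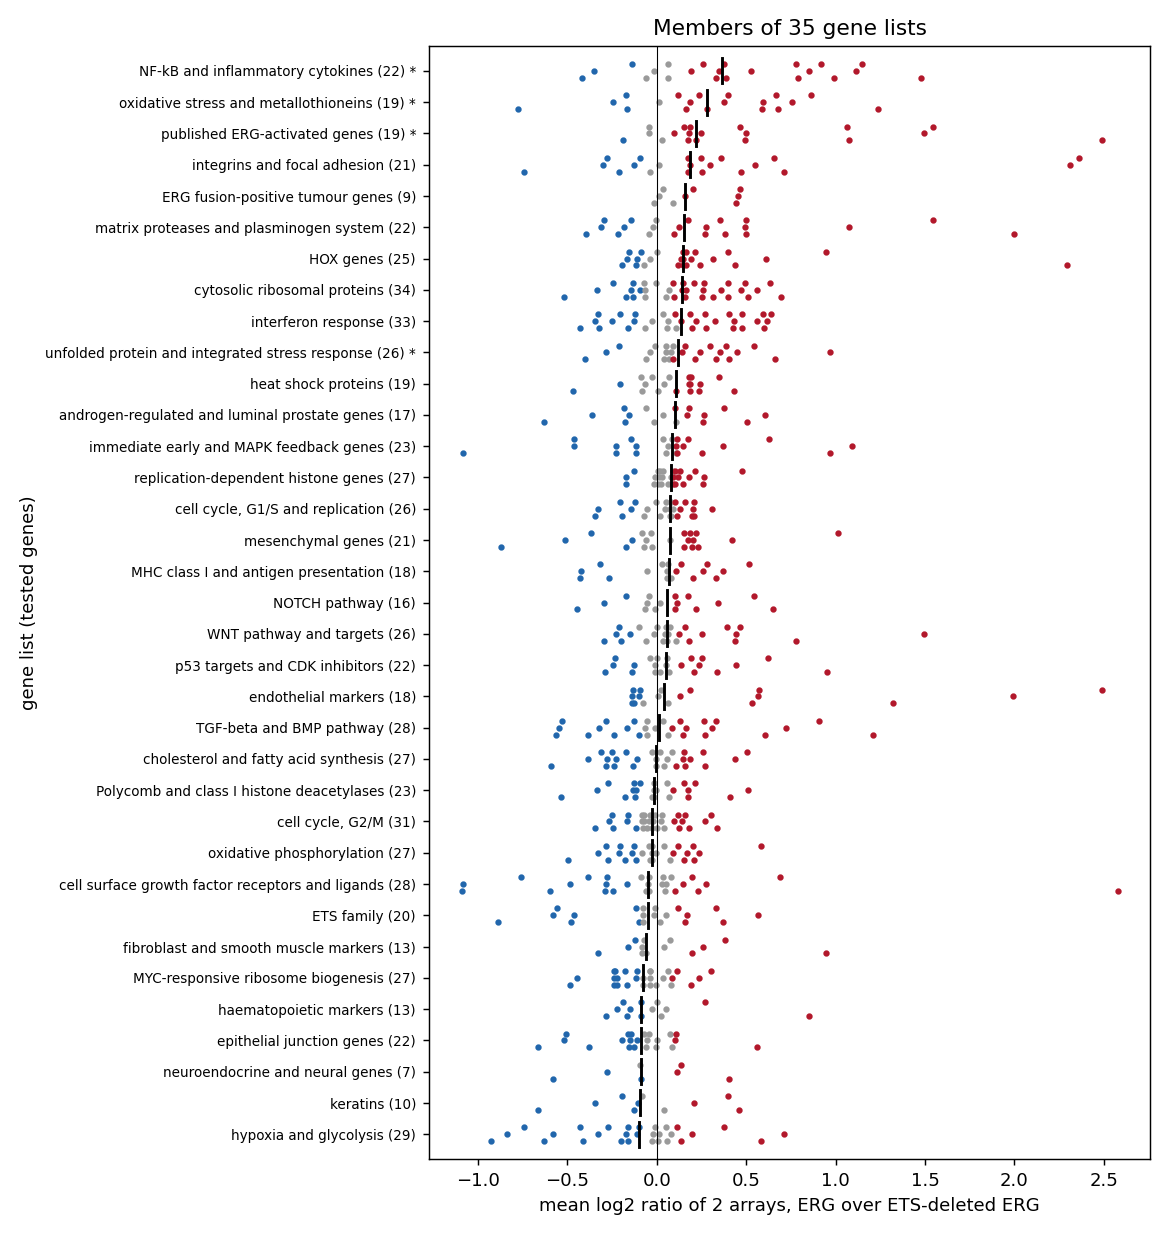
Each dot is a tested gene of a list, placed by its mean log2 ratio of ERG over ETS-deleted ERG (x axis, mean of 2 arrays) and coloured red if called higher, blue if called lower and grey if not called. Black bars are list medians, numbers in brackets count tested genes, and an asterisk marks the 4 lists with an adjusted camera p under 0.05 at the preset correlation.

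None of the other 31 lists passed the camera test. Members of several still moved by large amounts, and the counts that follow are of single genes. For scale, 6105 of all 17944 tested genes were called higher and 5263 lower. The plasminogen system and its proteases had 13 of 22 higher and 6 lower (adjusted p = 0.125), with SERPINB2, an inhibitor of plasminogen activators, at 1.995 ± 0.067 and PLAUR, the urokinase receptor, at 0.50 ± 0.0099 beside PLAT and MMP9. Among integrins and focal adhesion genes 13 of 21 rose and 6 fell (adjusted p = 0.108): LAMB3 was at 0.71 ± 0.046 beside ITGB3 and TGFBI, and ITGB4, the integrin of hemidesmosomes, at -0.74 ± 0.058. Mesenchymal genes split into 10 higher and 5 lower of 21 (adjusted p = 0.717), with COL5A1 at 1.01 ± 0.11 and SNAI2 at 0.42 ± 0.026 against fibronectin (FN1) at -0.87 ± 0.0014 and COL6A1 at -0.51 ± 0.02. Epithelial junction genes had 11 of 22 lower and 3 higher, or 11 and 4 adjusted over the list alone (adjusted p = 0.108), with LSR at -0.66 ± 0.057, CLDN4 at -0.52 ± 0.029 and SPINT1 at -0.51 ± 0.051, while TJP1 was at 0.56 ± 0.0072. Of 10 tested keratins, 5 fell and 3 rose (adjusted p = 0.597): KRT7 stood at -0.67 ± 0.015, KRT4 at -0.35 ± 0.062, KRT80 at 0.46 ± 0.014 and KRT18 at 0.40 ± 0.024, whose other probes lay between -0.09 and 0.15.

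Signalling lists moved in both directions, as the tested genes did as a whole (6105 higher and 5263 lower of 17944). WNT pathway genes had 10 of 26 higher and 5 lower (adjusted p = 0.235). LEF1 led, followed by NKD2 (0.78 ± 0.031, but -0.03 on its other probe), FZD7 (0.47 ± 0.04) and the secreted inhibitor DKK1 (0.44 ± 0.022), while the WNT target AXIN2 (-0.10) did not pass. The TGF-beta and BMP list had 12 higher and 10 lower of 28 (adjusted p = 0.888), with the ligands TGFB2 (1.21 ± 0.039) and INHBA (0.72 ± 0.015) and the targets ID3 (0.90 ± 0.038) and PMEPA1 (0.60 ± 0.016) higher. Of 23 immediate early and MAPK feedback genes, 10 rose and 8 fell, or 12 and 8 adjusted over the list alone (adjusted p = 0.597), with the phosphatase DUSP1 at 1.09 ± 0.034 and SPRY4 at 0.63 ± 0.024 beside ATF3 and, lower, AREG. The NOTCH list had 8 higher and 3 lower of 16 (adjusted p = 0.597), with NOTCH2 at 0.65 ± 0.037, HES1 at 0.54 ± 0.024, HES2 at 0.34 ± 0.013 and RFNG at -0.45 ± 0.0019. Growth factor receptors and ligands had 11 lower and 7 higher of 28 (adjusted p = 0.243). IGFBP5 was the highest, and FGFBP1, AREG and IGFBP4 (-0.76 ± 0.023) were the lowest. In the ETS family itself 6 of 20 rose and 7 fell (adjusted p = 0.463): FLI1, the closest relative of ERG, stood at 0.56 ± 0.013, and ELF3 (-0.89 ± 0.046), ELK1 (-0.58 ± 0.061) and SPDEF (-0.56 ± 0.055) were lower.

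HOX genes had 16 of 25 higher and 6 lower (adjusted p = 0.108), with a median of 0.15 whose sign, taken relative to all genes, turned under median centring. The list was shifted upward with the gene density trend removed (adjusted p = 0.0146) and with only spots flagged as feature outliers left out (adjusted p = 0.0497). The 6 tested genes from HOXB2 to HOXB9 all rose, with a median of 0.52 against 0.12 for the other 19, a grouping chosen after the values were seen. HOXB3 stood at 0.94 ± 0.048, HOXB5 at 0.44 ± 0.015 and HOXB6 at 0.61 ± 0.071, though the other HOXB6 probe gave -0.02 and the other HOXB3 probe 0.18, and HOXB13 was at -0.16. Interferon-stimulated genes had 18 of 33 higher and 9 lower, or 19 and 9 adjusted over the list alone (adjusted p = 0.125), among them MX1 (0.64 ± 0.03), USP18 (0.62 ± 0.011), IFIT2 (0.60 ± 0.075) and the RNA sensor IFIH1 (0.56 ± 0.01). Antigen presentation genes had 8 higher and 4 lower of 18 (adjusted p = 0.452), with ERAP2 at 0.51 ± 0.054 and HLA-C at 0.37 ± 0.015 against the immunoproteasome subunits PSMB8 (-0.43 ± 0.036) and PSMB10 (-0.43 ± 0.031). Chromatin repressors of the Polycomb and deacetylase list had 7 higher and 9 lower of 23 (adjusted p = 0.714), with JARID2 at 0.41 ± 0.056, RING1 at -0.54 ± 0.048 and HDAC3 at -0.33 ± 0.009. Of 27 histone genes 12 rose and 3 fell, or 10 and 3 adjusted over the list alone (adjusted p = 0.203), with H4C3 at 0.48 ± 0.099, H1-2 at 0.26 ± 0.0076, H4C8 at 0.21 ± 0.051 and H2BC21 at 0.26 ± 0.023, whose other probe gave -0.17.

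Cell cycle genes moved little. The G1/S list had 9 higher and 6 lower of 26 (adjusted p = 0.597), from CDT1 at -0.35 ± 0.033 and CCND3 at -0.33 ± 0.021 to E2F2 at 0.21 ± 0.0079, whose other probe gave -0.10, and RRM2 at 0.31 ± 0.039. The G2/M list had 9 higher and 7 lower of 31 (adjusted p = 0.601), from the kinase AURKB at -0.35 ± 0.063 to PRC1 at 0.27 ± 0.0054, CENPF at 0.30 ± 0.033 and CENPE at 0.34 ± 0.0077, and MKI67 did not pass (0.0029). Genes known as p53 targets or CDK inhibitors had 9 higher and 5 lower of 22 (adjusted p = 0.367), with PLK2 at 0.95 ± 0.05, FAS at 0.62 ± 0.0014, TNFRSF10B at 0.44 ± 0.041 and CDKN1A at 0.34 ± 0.011. PC3 cells carry no working p53. Of 29 hypoxia and glycolysis genes, 15 fell and 6 rose (adjusted p = 0.108): carbonic anhydrase 9 (CA9) was at -0.93 ± 0.015, PFKL at -0.84 ± 0.014 and PFKFB4 at -0.75 ± 0.025, while adrenomedullin (ADM) was at 0.71 ± 0.0026. Their median, -0.10, turned positive relative to all genes under median centring, and the list was shifted downward in 3 alternatives (adjusted p = 0.00964 to 0.036). Cholesterol and fatty acid synthesis had 9 higher and 11 lower of 27, or 10 and 11 adjusted over the list alone (adjusted p = 0.639), with MVD at -0.59 ± 0.0061, PMVK at -0.38 ± 0.052, SCD at -0.31 ± 0.045 (other probes -0.34 and 0.04) and the sterol carrier STARD4 at 0.50 ± 0.048.

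Respiratory chain genes had 8 higher and 10 lower of 27 (adjusted p = 0.486), and the subunits of succinate dehydrogenase parted, with SDHA at 0.58 ± 0.003, SDHC at -0.50 ± 0.018 and SDHD at -0.27 ± 0.047, beside COX4I1 at -0.33 ± 0.03, whose other probe gave 0.014. Cytosolic ribosomal proteins had 20 higher and 8 lower of 34 (adjusted p = 0.108), and their median, 0.14, fell below that of all genes in the scanner software's processed signals. The list was shifted upward in 5 other alternatives, among them median centring (adjusted p = 0.000165) and the gene density trend removed (adjusted p = 0.0325). RPL38 (0.63 ± 0.075) and RPL35 (0.56 ± 0.036) rose and RPS9 (-0.52 ± 0.025) fell. RPS2 was at 0.69 ± 0.022 on its brightest probe and between -0.46 and -0.06 on the others. Ribosome biogenesis genes responsive to MYC had 12 lower and 5 higher of 27 (adjusted p = 0.125), with PPAN at -0.48 ± 0.031, PES1 at -0.45 ± 0.081 and BOP1 at -0.24 ± 0.015 against GNL3 at 0.31 ± 0.044. Their median relative to all genes also turned under median centring, and the list was shifted downward with the mean of all probes (adjusted p = 0.0475). Heat shock proteins had 10 higher and 2 lower of 19, or 10 and 4 adjusted over the list alone (adjusted p = 0.274), with HSPE1 at 0.43 ± 0.085, HSP90AA1 at 0.35 ± 0.013, HSPH1 at 0.24 ± 0.024 and the co-chaperone BAG3 at -0.47 ± 0.017.

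Markers of other cell types were set beside these values. Endothelial genes, a cell type in which ERG is normally expressed, had 8 higher and 6 lower of 18 (adjusted p = 0.256). PECAM1 was at 1.99 ± 0.039, ICAM2 as above, FLI1 at 0.56 and FLT1 at least 2.5-fold higher, its control channel being not well above background. ESAM (-0.13) and ENG (-0.10) fell, EGFL7, the brightest member, was at 0.02 ± 0.035, and VWF, CDH5 and TEK were well above background on at most 1 array, in the ERG channel. Fibroblast and smooth muscle markers had 4 higher and 3 lower of 13 (adjusted p = 0.964), with a median of -0.06 but a mean of 0.08 and an upward test. COL6A3 was at 0.95 ± 0.0045, ACTG2 at 0.38 ± 0.011, PDPN at 0.26 ± 0.09, PDGFRA at -0.33 ± 0.028 and FBLN1, the brightest, at 0.04 ± 0.024 and -0.35 on its other probe. Haematopoietic markers had 2 higher and 7 lower of 13 (adjusted p = 0.431), with ITGAX at least 1.7-fold higher, FCER1G at 0.27 ± 0.051, CORO1A at -0.28 ± 0.13, CD3E at -0.19 ± 0.0056 and LCP1, the brightest, at -0.09 ± 0.0075. Of the neuroendocrine list 7 of 23 members were measurable, 3 higher and 3 lower (adjusted p = 0.639), with ENO2 at -0.58 ± 0.013, CHGA at -0.28 ± 0.081, SCG5 at 0.14 ± 0.078, PCSK1 at least 1.19-fold higher and TUBB3, the brightest, at -0.09 ± 0.0069. Androgen-regulated and luminal prostate genes had 8 higher and 5 lower of 17, or 9 and 5 adjusted over the list alone (adjusted p = 0.597), with FOLH1 at 0.51 ± 0.018, FOXA1 at 0.38 ± 0.0099 and PMEPA1 higher and NDRG1, the brightest, at -0.63 ± 0.012. In the lists for which no such count is given, the count adjusted over the list alone equalled that over all genes. Bounds written "at least" set the ERG channel against the higher of the control signal of that probe and the lowest signal well above background, and stay open to dye bias.

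Ratios also followed position in the genome, a comparison chosen after the values were seen. Among genes with at most 11 array genes within 500 kb on either side, 1670 were called higher and 793 lower, and among those with 35 or more, 626 were higher and 1632 lower. Across 17866 genes the rank correlation of the mean ratio with this local gene density was -0.241, and it was -0.232 on array 1 and -0.240 on array 2. The lowest window of 40 neighbouring genes lay on chromosome 11 from 63500477 to 64645634 (hg18), where 33 genes were called lower and 1 higher, with a median of -0.30. A window on chromosome 6 from 32256335 to 33771750 had a median of -0.21. The highest window lay on chromosome 1 from 173250284 to 181484404, where 27 genes were called higher and 4 lower, with a median of 0.19. The same ordering held among called genes of at least 1.5-fold (rank correlation -0.305).

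**Figure D4:**
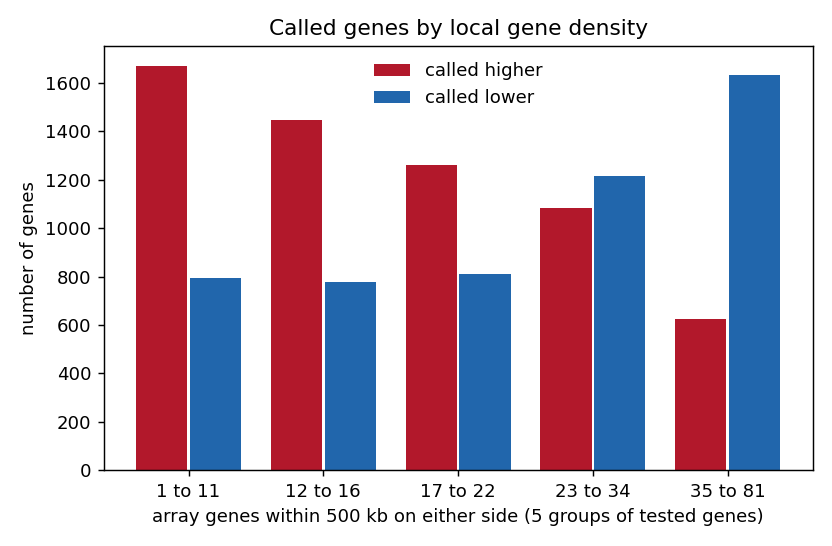
Bars count the genes called higher (red) and lower (blue) with ERG over ETS-deleted ERG (y axis) in 5 groups of tested genes with increasing local gene density, the number of array genes within 500 kb on either side (x axis). Higher calls fall from 1670 to 626 and lower calls rise from 793 to 1632 between the sparsest and the densest group.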

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

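The all-spots background model, the feature-flag setting and the removal of the density trend were chosen after the data were examined. Signal over background limits which genes were tested: 60.2% to 66.6% of gene spots in a channel were well above it. Except where stated, the cause of a change was not tested.

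Genes changed, 11368, stayed within 1.5 times from 8550 (processed signals) to 14746 (median centring), with 12227 without background subtraction. The count fell to 1894 with the background model on all spots and feature flags only (11945 with those flags alone), to 4904 without the array as a replicate block and to 492 at 1.5-fold or more. Of the 11368 calls, 1790 were kept in the same direction by the all-spots model, 8073 by the processed signals and 6971 by median centring, which calls 2695 in the other direction. Median centring moved the median of all genes from 0.015 to 0.29 and gave 12648 higher and 2098 lower calls (85.8% higher, against 53.7%).

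Genes at least 2-fold on both arrays, 82, numbered 436 in the processed signals and 435 in the deposited table, 300 under median centring, 24 with the all-spots model and 428 at 1.5-fold. With 1 array alone, 86 to 93 genes reached 2-fold. The correlation of the arrays, 0.946, was 0.954 without background subtraction, 0.923 with offset 16, 0.880 in the processed signals and in the deposited table, 0.967 under median centring, 0.882 without the dim filter, 0.952 with both channels well above background, 0.944 with the mean of all probes (0.9435), 0.831 with the all-spots model and 0.943 without the density trend. No paired analysis beyond the array ratio was possible because the group has no separate control samples. With 1 array no calls, lists or correlation can be had, and no spot was saturated.

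Of 35 gene lists 4 were shifted; the number was 2 with offset 16, in the processed signals and in the deposited table, 10 under median centring, 7 with the all-spots model, 9 with feature flags only, 8 without the density trend and 0 with an estimated correlation, where limma's camera gave 0 lists at an unadjusted p under 0.05 (smallest 0.164). limma's fry, which tests each list against no change, called 1, the immediate early list (adjusted p = 0.0387), and none of the 4. Its adjusted p was 0.0637 for the ERG-activated, cytokine and oxidative stress lists and 0.0925 for the unfolded protein list. The fry test too has only 1 residual degree of freedom, so neither its call nor these losses decide anything. By camera, lists outside the 4 passed in some alternatives: ribosomal proteins in 5, integrins and hypoxia in 3 each, HOX and histones in 2 each, and epithelial junction, interferon, G1/S, p53, MYC-responsive and haematopoietic in 1 each. Across 17 alternatives the published ERG-activated and the cytokine list each kept the call in 15, oxidative stress in 11 and the unfolded protein response in 10. Relative to all genes, the medians of 22 lists kept their sign under 4 other scalings. Median centring turned 11 lists: mesenchymal, TGF-beta and BMP, G2/M, HOX, cholesterol, hypoxia, Polycomb, MYC-responsive, oxidative phosphorylation, NOTCH and endothelial. The density trend turned keratins, and the processed signals ribosomal proteins.

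ERG probe A_23_P301414 went from -0.08 to 0.23 under median centring (-0.067 relative to all genes) and to -0.14 without the density trend (adjusted p = 0.00796; range over alternatives 0.000425 to 0.493). Probe A_23_P57323 went from 0.02 to -0.11 in the processed signals and -0.24 under median centring. Probe A_24_P922378 went from 0.84 to 0.46 with the all-spots model (adjusted p = 0.201; range 5.63e-53 to 0.201). On single arrays they ranged from -0.09 to -0.06, -0.03 to 0.08 and 0.81 to 0.86.

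Of 2151 values of 154 named genes under alternatives with a test, 2034 kept direction and side of the threshold, 91 lost the call, 6 gained one and 20 turned sign. Of the 91 lost calls, 60 fell to the all-spots model with feature flags only, under which 94 of the 154 genes stayed the same. On single arrays 307 of 308 had the sign of the mean, all but EGFL7. Under median centring AURKB (0.058), BOP1 (0.35), CCND3 (0.094), CDT1 (0.19), COX4I1 (0.34), ERG (0.23), HDAC3 (0.066), LCP1 (0.40), NDRG1 (0.026), PMVK (0.15), PPAN (0.0093), PSMB10 (0.087), PSMB8 (0.014), RPS9 (0.15), SCD (0.12), SDHD (0.24) and TUBB3 (0.49) became positive, though relative to all genes only BOP1, COX4I1, LCP1 and TUBB3 (4 of 17) turned. With the mean of all probes ERG went to 0.38, FBLN1 to -0.16 and RPS2 to -0.034, since their probes differ.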

Other observations

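The genes of the next paragraph, and the tests on array spread, further probes, base composition and endothelial cells, were chosen after the results were seen. The bounds for copy number and for intensity were set before.

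The genes here are single examples among the 82 that differed at least 2-fold on both arrays, with no list or enrichment test behind them. SPOCK1, a matrix proteoglycan, stood at a log2 ratio of 1.88, EFEMP1 at 1.69, the hyaluronan-binding protein CEMIP at 1.63, the growth factor IGF2 at 1.58 and KISS1 at 1.56. TNFRSF11B, the decoy receptor of RANKL, was at 1.54 and BMP6 at 1.15. ECSCR was at least 3.44-fold higher, RHOJ at least 2.46-fold, GIMAP1 at least 2.11-fold and the chemokine CXCL12 at least 2.19-fold, each with its control channel not well above background. GIMAP6 stood at 1.42, the exchange factor DOCK8 at 1.37, and THBD, the thrombomodulin gene, at 1.08. ANK1, an ankyrin of red cells, was at 1.94 and DYSF, a membrane-repair protein of muscle, at 1.85.

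Most tested genes were called, and 95.7% of calls were under 1.5-fold. The arrays differed by 0.974 times what spot noise gives, so the test holds no spread beyond spot noise, and calls at such sizes are consistent with hybridisation precision alone setting the threshold. That probe-specific effects are the whole cause is argued against by further probes of the same gene: 72.9% (2242 of 3074, 95% Wilson interval 71.3 to 74.5) had the same sign, against 53.6% of genes that were not called. At 1.5-fold or more 94.7% of 150 did. A difference between the 2 RNA preparations, or a dye effect shared by both arrays, stays open beside an effect of ERG, since the design holds neither a dye swap nor a separate culture known as such.

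Ratios fell with local gene density (rank correlation -0.241, against -0.025 to 0.031 in 1000 shuffles). The shuffles treated genes as independent. Neighbouring genes share much of their density window and can move together, so that range is too narrow. Copy number differences between the cell populations are argued against as the whole cause, since the correlation was negative within 22 of 23 chromosomes, from -0.379 on chromosome 11 to 0.02 on chromosome 13. The correlation was also negative in 10 of 10 intensity deciles (-0.291 to -0.140), past the bound set against an intensity-dependent dye effect. That outcome was likely beforehand, since loess had already removed trends with intensity and mean intensity hardly followed density (rank correlation 0.086). The deciles therefore add little to the loess correction itself. Gene-dense regions are rich in G and C, and a labelling or dye effect of base composition may account for the trend: further probes of the same genes gave -0.315, which such an effect and a change in the cells would both give. The 2 cannot be told apart without a dye swap or probe sequences. Removing the trend left 11212 calls, 9593 of them among the original 11368 in the same direction.

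PECAM1, ICAM2 and FLT1 were at least 2-fold higher, and a candidate explanation is endothelial cells in the ERG culture, although nothing in the labels points to any. The 17 tested endothelial genes other than ERG had a median log2 ratio of 0.062 (bootstrap 95% range -0.098 to 0.565), below 1.5-fold, with 8 higher and 6 lower, and 2 of them also stand in the published ERG-activated list. Of 5 abundant endothelial transcripts only 2 were measured above background, ENG at -0.10 and ESAM at -0.13, while VWF, CDH5 and TEK lay too near background for a ratio. These values cannot tell whether such cells were present, since the bound used asked for more than 2 of the 5 to be measured. A high level of ENG or ESAM in PC3 cells would also hide a small share. Activation of part of the endothelial programme by the ETS domain stays a hypothesis too, untested against a shared dye effect.

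The deposited log2 table has its columns crossed against the scanner tables: each column matched the other array with r = 0.999 and its own with 0.667 and 0.668. Spike-in RNAs covered log2 ratios from -3.68 to 2.44 on array 1 and from -3.73 to 2.47 on array 2. In order of ratio, the middle kinds stood at -0.73 and -0.31 on array 1 and at -0.75 and -0.30 on array 2. On array 1 the lower kinds stood at -3.68, -2.12, -2.03 and -1.93 and the higher at 0.72, 0.99, 1.11 and 2.44. These values are not symmetric about 0. Designed ratios were not set beside them, so whether the spike-ins are centred on 0 was not checked. The split of small calls into higher and lower rests on where 0 lies.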
